A study of Homo sapiens with 9 samples.

How the data were processed

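Gene expression was measured on 9 Illumina expression arrays, each with total RNA of HCC4006, an established lung adenocarcinoma line that carries a mutant epidermal growth factor receptor (EGFR). The labels give 3 groups of 3 arrays. The parental group holds cells that had not been selected. The resistant group was kept for 6 months in rising concentrations of gefitinib, an EGFR kinase inhibitor. The inhibitor group had gefitinib for 6 months together with SB431542, a small molecule that blocks the type I TGFβ receptor kinase. Per the labels' protocols, RNA was isolated with Trizol, cleaned on RNeasy columns with DNase I, checked on a Bioanalyser, and turned into biotin-labelled cRNA with an Ambion MessageAmp kit. The sample titles call these cells gefitinib resistant and inhibitor treated, while the series design gives the compounds in combination, so it is open whether resistance came before the inhibitor. They state neither whether replicates of a group were separate cultures nor whether either compound was present at harvest. The p-values therefore measure the spread between these arrays, which may be technical. No group had SB431542 alone, and none is labelled as kept for 6 months without gefitinib. Effects of the compounds, of a possible separate selection and of time in culture can therefore not be told apart. Where the text speaks of an inhibitor change, it means the difference between these groups.

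The deposited table holds 1 intensity per gene symbol and array, on a linear scale, with values from 72.65 to 11566.7. The 9 array medians lay between 91.1 and 91.3. The sorted values of each array differed from their mean over the 9 arrays by at most 0.0178 on the log2 scale. The deposited intensities had therefore already been quantile-normalized. The values were not centred. Since no value came near 0, background had not been subtracted. The scanner, the software and the way several probes of a gene were combined are not given in the sources used here. As a stand-in for background, the 95th percentile of 375 olfactory receptor rows was taken, which was 90.3; 52.9% of genes had a mean over the 9 arrays above it. Because background stayed in the intensities, a fold change of a gene that was near 90 in one group is understated, and small changes near that level carry little. The number of arrays limits the precision.

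Of 34687 rows, 3270 named only a UniGene cluster and were left out of the main tests. Older names were updated with the RefSeq gene table of assembly GRCh38.p14, used for names only. In it, 17757 rows matched by current symbol, 2669 by gene number and 3303 by an older symbol, and the other 7688 kept the name in the table. Where several rows named one gene, the row with the highest mean over the 9 arrays was used, which left 30672 genes, 728 of them with more than 1 row. EPCAM is listed as TACSTD1, ESRP1 as RBM35A, ACKR3 as CXCR7 and CXCL8 as IL8. Probe sequences and genome positions were not used here.

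Values were taken to log2 (a planned floor of 16 changed no value) and fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group over all 9 arrays, an intensity trend in the variance prior, and Benjamini-Hochberg adjustment over the 30672 genes of each comparison. A gene was called at an adjusted p under 0.05. A second count took called genes with a change of at least 2-fold. Unless another test is named, adjusted p-values are from limma. Log2 changes are differences of group means and are given ± SE; intensities are given as mean ± SD over the 3 arrays of a group. Figures were drawn with matplotlib 3.10.9.

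Comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The 22 lists were epithelial markers, mesenchymal markers, TGFβ targets, ERK pathway output, the ERBB family, bypass receptors, proliferation, lung lineage, neuroendocrine markers, squamous and basal markers, interferon response, antigen presentation, integrins and laminins, cholesterol synthesis, hypoxia and glycolysis, stress response, detoxification, cytokines, YAP targets, the BCL2 family, leukocyte markers and endothelial markers. The last 2 stand for other cell types. CDK1 was the 1 list member not matched to a row. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists of a comparison. Camera with an estimated correlation, and the count of members called when adjusted over the list alone, are given beside it. Named genes are the 6 largest rises and 6 largest falls of each comparison among called genes whose groups did not overlap and whose brighter group mean was above the median of all rows. They include a panel of 17 genes taken whatever their result, up to 4 called members with the largest change per list described, and 6 genes each that were called the opposite way or that stayed different from parental with the inhibitor. Some genes that this rule takes are not reported here. ACTA2, CALD1, ID3, TAGLN, KRT8, KRT18, MCM6, PCNA and FOXA2 are named in at least 1 comparison outside this rule, chosen after their values were seen.

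The first and second comparison share the resistant arrays, which by itself gives opposite signs. Groups without any change, and groups with the measured resistance changes but no inhibitor effect, were therefore simulated in 100 draws each. The fitting code was tested on simulated data of 30672 genes with seeded changes. In resistant against parental cells it recovered 94.0% of changes of 0.5 on the log2 scale and 100% of changes of 1 and 2, with 13 false calls; with the inhibitor against resistant cells the shares were 85.1%, 100% and 100%, with 12 false calls.

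Alternatives were cyclic loess scaling (the values being quantile-normalized already), arrays shifted to one median, dim genes left out, 50 added to the intensities, the mean of a gene's rows, a variance prior without trend or robust, only the arrays of the groups compared, the replicate number as a block, an adjusted p under 0.01 and each array left out in turn. Normexp background correction with an offset of 50, the UniGene rows kept, and the counts of genes outside both other groups without inhibitor replicate 2 were added after seeing the data. Leaving out each array was run then too for the counts of list members and for the genes named outside the rule above; those genes were run under no other alternative. The labels number replicates alike in each group without saying that a number marks a pair, and the numbers were not used in the main tests.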

Results

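Transcript levels were compared between parental HCC4006 cells, cells made resistant by 6 months in gefitinib, and cells given gefitinib for 6 months in combination with the TGFβ receptor inhibitor SB431542, with 3 arrays per group. The median intensity of the arrays was 91.1 to 91.3. Arrays of one group correlated at 0.996 to 0.998 over all genes, except for inhibitor replicate 2, which correlated at no more than 0.991 with the other arrays of its group. In that array 54 genes deviated at least 2-fold from the mean of the other inhibitor arrays, against 3 genes in replicate 1 and 3 in replicate 3. The first principal component held 55.4% of the variance and separated resistant from parental arrays, with the inhibitor arrays between them. The second held 29.3% and set the inhibitor arrays apart from both.

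The first comparison asked what had changed in resistant cells. Mesenchymal markers rose (20 of 30), and epithelial (27 of 34) and lung lineage genes (12 of 16) fell, with camera adjusted p-values of 1.17e-11 or less. FLNC, which encodes an actin cross-linker, rose by 4.90 ± 0.13 on the log2 scale (29.9-fold, adjusted p = 1.26e-15), from 115 ± 5.17 in parental to 3443 ± 356 in resistant cells (SD, n = 3). The secretoglobin gene SCGB3A1 fell by 5.06 ± 0.09 (adjusted p = 3.7e-17), from 3766 ± 67.8 to 113 ± 2.74. CDH2, which encodes N-cadherin, rose by 1.94 ± 0.10, and CDH1, which encodes the epithelial adhesion protein E-cadherin, fell by 1.43 ± 0.12.

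Other large rises were those of the tight junction gene CLDN11 (4.16), the collagen gene COL8A1 (4.09), the chemokine receptor gene ACKR3 (3.74) and the BMP antagonist GREM1 (3.59). The other large falls were those of HOPX (-4.61), the matrix Gla protein gene MGP (-4.37), the cystatin genes CST1 (-4.21) and CST4 (-3.88), and the tetraspanin gene TSPAN8 (-3.79). The highest adjusted p among these genes was 8.12e-15. COL8A1 and ACKR3 lay within background in parental cells, and CST1 and CST4 lay at 90.5 and 93.2 in resistant cells, so their changes are understated. Over all 30672 genes, 3143 were called higher and 3132 lower in resistant cells (20.5%). Of these, 319 were at least 2-fold higher and 469 at least 2-fold lower. Inhibitor replicate 2 enters this comparison only through the shared estimate of spread. Without it, 3983 genes were higher and 3688 lower, and 319 and 469 were so by at least 2-fold.

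Among 34 epithelial markers, 27 fell, 2 rose and 5 did not pass; adjusted over the list alone, 29 fell and 2 rose. Camera gave an adjusted p of 3.03e-26 for a downward shift (adjusted p = 0.000918 with an estimated correlation). The protease gene PRSS8 fell by 2.67, the small GTPase gene RAB25 by 2.62, the claudin gene CLDN7 by 2.55 and the membrane traffic gene MAL2 by 2.35. CDH1 fell from 1935 ± 272 to 713 ± 46.7, and the adhesion gene EPCAM fell by 1.35 ± 0.09. The splicing regulator ESRP1 fell by 0.45 ± 0.06, from 124 to 90.4, close to background. The keratin genes KRT8 and KRT18 were the 2 that rose, by 0.70 and 0.58.

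Among 30 mesenchymal markers, 20 rose, 1 fell and 9 did not pass; adjusted over the list alone, 22 rose and 1 fell. The upward shift had a camera adjusted p of 4.88e-22 (adjusted p = 0.00065 with an estimated correlation). The methyltransferase gene NNMT rose by 3.40, EMP3 by 3.20, the collagen gene COL1A2 by 3.10 and the receptor tyrosine kinase gene AXL by 2.85 ± 0.14. Vimentin (VIM) rose by 1.87 ± 0.09, from 2069 ± 202 to 7565 ± 354, which lay above the 99th percentile of all values (5549), where the scale may be compressed. CDH2 rose from 650 ± 39.2 to 2499 ± 102. The transcription factor gene TWIST1 rose by 1.70 ± 0.07, from background to 295 ± 21.8. The smooth muscle actin gene ACTA2 was the 1 that fell, by 0.45, a call lost without resistant replicate 2 (adjusted p = 0.0586). FN1 (fibronectin) lay within background in all groups. ZEB1 passed the test with a change of 0.18 (adjusted p = 0.00157), but its means of 78.6 and 88.8 were both within background. SNAI2 changed by 0.33 ± 0.13 without passing (adjusted p = 0.0709), and it passed when inhibitor replicate 2 or 3 was left out (adjusted p = 0.01 and 0.038; range over 20 alternatives, 0.00964 to 0.222).

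Of 16 lung lineage genes, 12 fell and none rose, over all genes and adjusted over the list alone. The camera adjusted p was 1.17e-11 (adjusted p = 0.00201 with an estimated correlation). They included HOPX, the aspartic protease gene NAPSA (-3.34), the phosphate transporter gene SLC34A2 (-2.95) and the transcription factor gene FOXA1 (-1.92).

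**Figure D1:**
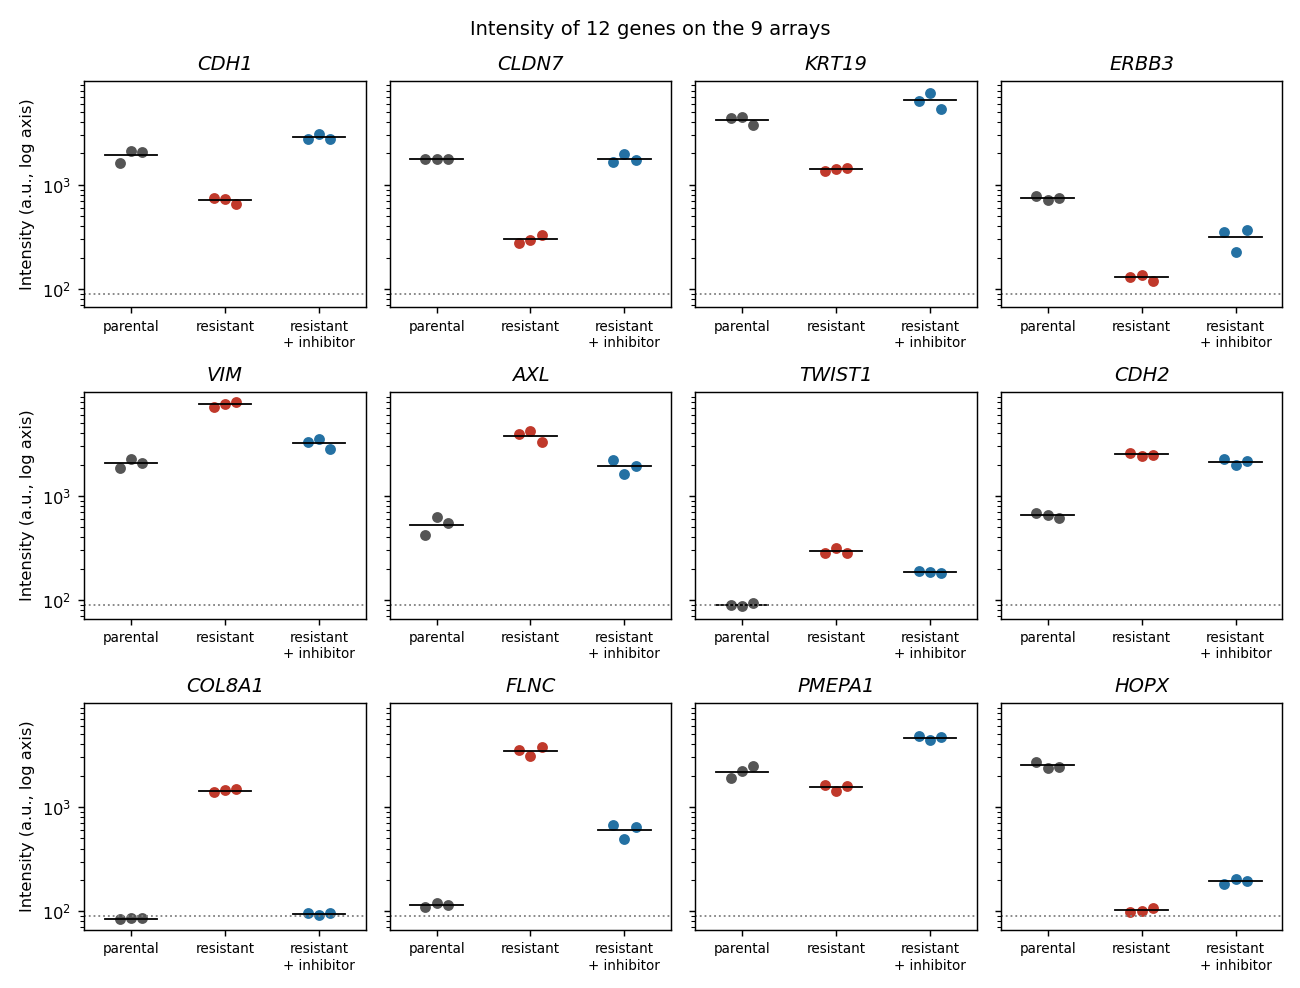
Array intensity (arbitrary units, log axis) of 12 genes in the parental, resistant and resistant plus inhibitor arrays; each point is 1 array, bars are group means and the dotted line marks the background level of 90.3. CDH1 fell from 1935 to 713 in resistant cells and stood at 2858 with the inhibitor, whereas CDH2 rose from 650 to 2499 and stood at 2134.

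In the ERBB family, 5 of 12 genes fell and 2 rose, over all genes and adjusted over the list alone. The receptor gene ERBB3 fell by 2.54 ± 0.14, from 749 ± 33.1 to 129 ± 8.85. The ligand genes HBEGF and NRG1 rose by 1.04 and 0.98, and the ligand gene TGFA fell by 1.02. EGFR itself fell by 0.59 ± 0.12 (adjusted p = 0.000925). The list's downward shift had a camera adjusted p of 0.0297 (adjusted p = 0.116 with an estimated correlation); it was lost without resistant replicate 1 (adjusted p = 0.0721) and with dim genes left out (adjusted p = 0.1; range over 20 alternatives, 0.0198 to 0.116). Of 16 ERK output genes, 10 fell and 3 rose in both counts, with a camera adjusted p of 0.000608 (adjusted p = 0.116 with an estimated correlation). The ERK phosphatase gene DUSP6 fell by 2.63 and the feedback inhibitor genes SPRY4 and SPRED1 by 1.58 and 1.18, while the AP-1 gene FOSL1 rose by 1.07. Of 20 bypass receptor genes, 4 rose and 3 fell (4 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.585). The 4 that rose became 2 without parental replicate 1 or resistant replicate 3. Besides AXL, the growth factor gene FGF2 rose by 0.85, and the receptor genes KIT and FGFR3 fell by 1.94 and 1.36. MET fell by 0.54 ± 0.16 (adjusted p = 0.0192). That call was lost without parental replicate 2 or 3 or resistant replicate 1 or 2 (adjusted p = 0.0529 to 0.133) and with a variance prior without trend (adjusted p = 0.0744; range over 20 alternatives, 0.000265 to 0.133).

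Of 28 TGFβ targets, 6 rose and 9 fell (7 and 11 adjusted over the list alone), and the list was not called (adjusted p = 0.233). The metalloprotease gene ADAM19 rose by 2.45, whereas ID1 fell by 2.27 and ANGPTL4 by 1.59. SMAD7, a feedback inhibitor of the pathway, rose by 0.30 ± 0.09 (adjusted p = 0.0134), a call lost without parental replicate 3 or resistant replicate 3 (adjusted p = 0.0726 and 0.0982; range over 20 alternatives, 0.00216 to 0.0982). The ligand gene TGFB2 fell by 0.37 ± 0.10 (adjusted p = 0.00874), a call lost without parental replicate 3 or resistant replicate 1 (adjusted p = 0.0635 and 0.0588; range over 20 alternatives, 0.00157 to 0.0635). TGFBI stood at 7841 ± 377 and 7957 ± 217 (log2 change 0.02, adjusted p = 0.864), above the 99th percentile of all values (5549), where the scale may be compressed.

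Of 22 interferon response genes, 12 fell and 3 rose (14 and 3 adjusted over the list alone; camera adjusted p = 7.91e-05). That call was lost at an adjusted p = 0.234 with an estimated correlation. IFI27 fell by 2.34, IFI44L by 1.18, OAS2 by 1.17 and OAS1 by 1.13. Of 15 stress response genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 7.91e-05, adjusted p = 0.0202 with an estimated correlation), led by DDIT4 (-1.45), TRIB3 (-1.31) and XBP1 (-0.98). Of 15 cholesterol synthesis genes, 8 fell (9 adjusted over the list alone; camera adjusted p = 0.00018, adjusted p = 0.0737 with an estimated correlation), among them IDI1 (-0.87) and FDFT1 (-0.65). None rose, but 1 did without parental replicate 2. Of 15 hypoxia and glycolysis genes, 7 fell and 2 rose in both counts (camera adjusted p = 0.00312, adjusted p = 0.0691 with an estimated correlation), with PFKFB3 at -1.52 and NDRG1 at -1.51. The 2 that rose became 1 without any 1 parental array or resistant replicate 1 or 2.

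Of 12 YAP targets, 5 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.000816, adjusted p = 0.0413 with an estimated correlation). CCN1 rose by 1.49, CRIM1 by 1.19 and NUAK2 by 0.74. The 5 that rose became 8 without inhibitor replicate 2, and the 2 that fell became 1 without any 1 parental or resistant array. Of 20 integrin and laminin genes, 9 rose and 3 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.0132, adjusted p = 0.201 with an estimated correlation). The laminin gene LAMA4 rose by 2.68 and ITGA5 by 1.44, while ITGA2 fell by 1.31 and ITGAV by 1.24. Of 22 proliferation genes, 9 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.0168, adjusted p = 0.234 with an estimated correlation). The risers included the mitotic genes AURKA (1.07), AURKB (1.00), BIRC5 (0.89) and CDC20 (0.83), and the 3 that fell included MCM6 (-0.80) and PCNA (-0.52), which serve DNA replication. Of 13 BCL2 family genes, 3 rose and 1 fell in both counts (camera adjusted p = 0.04, adjusted p = 0.118 with an estimated correlation); the proapoptotic genes BAX, HRK and PMAIP1 rose by 0.83, 0.60 and 0.55. The 1 that fell was lost without parental replicate 1 or 2 or resistant replicate 2. With dim genes left out, these last 3 lists were no longer called (adjusted p = 0.0685, 0.0875 and 0.138). Over 20 alternatives, the adjusted p ran from 0.00592 to 0.201 for integrins and laminins, from 0.00455 to 0.234 for proliferation and from 0.0191 to 0.138 for the BCL2 family. The proliferation call was also lost without parental replicate 1 (adjusted p = 0.0598), and the BCL2 call without resistant replicate 1 or 3 (adjusted p = 0.0727 and 0.0681) and with loess scaling (adjusted p = 0.0505).

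Of the other lists, none was called in this comparison. Detoxification genes split, with 5 of 17 higher and 4 lower in both counts (adjusted p = 0.658; median -0.0072, mean 0.013, test upward). AKR1C3 rose by 2.25 and ALDH1A3 fell by 1.75. Cytokine genes split likewise, with 4 of 20 higher and 4 lower (6 and 5 adjusted over the list alone; adjusted p = 0.957). Without parental replicate 3, 2 were higher. IL11 rose by 2.68 and CXCL8 fell by 2.56. Among squamous and basal markers 3 of 12 rose and 2 fell in both counts (adjusted p = 0.985), with SOX2 at -1.10. Antigen presentation genes had 2 of 12 higher in both counts (adjusted p = 0.585). Of these genes 1 was higher without parental replicate 2 or 3 or resistant replicate 2, and none without resistant replicate 3. There TAP2 had an adjusted p of 0.0775 (range over 20 alternatives, 0.00321 to 0.0976) and PSMB9 of 0.0596 (range over 20 alternatives, 0.00156 to 0.0596). Without inhibitor replicate 2, 1 was lower. Neuroendocrine markers had 2 of 10 higher (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.695). Over all genes none was lower, but 1 was without inhibitor replicate 2. Leukocyte markers had 1 of 12 higher and 2 lower in both counts (adjusted p = 0.305). Endothelial markers had 2 of 10 lower in both counts (adjusted p = 0.334). These became 1 without parental replicate 3 or resistant replicate 2.

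The second comparison asked how cells given gefitinib and the TGFβ receptor inhibitor differed from resistant cells. Epithelial markers rose (30 of 34) and mesenchymal markers fell (17 of 30) relative to resistant cells, with camera adjusted p-values of 1.01e-14 or less. TCN1, which encodes a cobalamin-binding protein, rose by 3.43 ± 0.11 on the log2 scale (10.7-fold, adjusted p = 5.55e-14), from 133 ± 2.06 to 1433 ± 129 (SD, n = 3). COL8A1 fell by 3.92 ± 0.08 (adjusted p = 3.09e-16), from 1442 ± 56 to 95.1 ± 1.91. CDH1 rose by 2.00 ± 0.12, to 2858 ± 210, and CDH2 changed by only -0.23 ± 0.10 (adjusted p = 0.148).

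The other large rises were those of the interferon-induced gene IFI27 (3.04), the endoplasmic reticulum gene ERP27 (2.93), the adhesion gene MPZL2 (2.77), the ribonuclease gene RNASE1 (2.75) and PROM2 (2.72). The other large falls were those of ACKR3 (-3.51), NNMT (-3.48), EMP3 (-3.35), BEX1 (-3.29) and CLDN11 (-3.14). Over all genes, 2664 were called higher and 2704 lower with the inhibitor (17.5%), of which 324 were at least 2-fold higher and 223 at least 2-fold lower. Without inhibitor replicate 2, the array that correlated less with its group, 2653 were higher and 2709 lower, and 315 and 199 were so by at least 2-fold.

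Of the 34 epithelial markers, 30 rose and none fell, over all genes and adjusted over the list alone. The camera adjusted p was 1.42e-39 (adjusted p = 0.000558 with an estimated correlation). CLDN7 rose by 2.57, MAL2 by 2.49, RAB25 by 2.44 and the transcription factor gene OVOL2 by 2.37. EPCAM rose by 1.43 ± 0.09, to a level in the range that may be compressed, and ESRP1 by 0.44 ± 0.06, from 90.4 to 123. Of the 30 mesenchymal markers, 17 fell and 2 rose (18 and 2 adjusted over the list alone; camera adjusted p = 1.01e-14, adjusted p = 0.0011 with an estimated correlation). After NNMT and EMP3, COL1A2 fell by 3.08 and THY1 by 2.29. VIM fell by 1.24 ± 0.09, to 3219 ± 344, from a resistant level in the range that may be compressed, AXL by 0.97 ± 0.14 and TWIST1 by 0.66 ± 0.07. The actin-associated genes CALD1 and ACTA2 were the 2 that rose, by 0.87 and 0.41. The ACTA2 call was lost without any 1 resistant array or inhibitor replicate 1 or 3 (adjusted p = 0.0531 to 0.134). CDH2 passed only with a variance prior without trend (adjusted p = 0.0265; range over 20 alternatives, 0.0265 to 0.371). SNAI2 changed by 0.10 ± 0.13 (adjusted p = 0.705). FN1 and ZEB1, both within background, had adjusted p-values of 0.825 and 0.129.

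Of the 22 interferon response genes, 17 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 3.16e-18). That call ended at an adjusted p = 0.0562 with an estimated correlation. IFI27 went from 679 ± 101 to 5566 ± 453, just above the 99th percentile of all values (5549), OAS2 rose by 1.78, OAS3 by 1.49 and IFI44L by 1.29.

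Of the 28 TGFβ targets, 15 rose and 4 fell (17 and 4 adjusted over the list alone; camera adjusted p = 2.83e-05, adjusted p = 0.0369 with an estimated correlation). Those that fell included ID2 (-2.46), ID3 (-1.18) and the actin-binding gene TAGLN (-0.78). ID1 rose by 1.88, the integrin gene ITGB6 by 1.75 and PMEPA1, a feedback inhibitor of the pathway, by 1.58. TGFB2 rose by 0.41 ± 0.10 (adjusted p = 0.00459). SMAD7 (0.12, adjusted p = 0.425) and TGFBI (0.01, adjusted p = 0.923) did not pass.

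Of the 16 ERK output genes, 9 rose and 2 fell in both counts (camera adjusted p = 9.18e-05, adjusted p = 0.0927 with an estimated correlation). DUSP6 rose by 1.85, the cyclin gene CCND1 by 0.80, PHLDA1 by 0.79 and SPRY4 by 0.72. Without resistant replicate 1, 1 fell. In the ERBB family 5 of 12 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.013, adjusted p = 0.0927 with an estimated correlation), with TGFA at 1.56, ERBB3 at 1.25 ± 0.14, ERBB2 at 1.03 and HBEGF at -0.76. In that family 2 fell without resistant replicate 1 or inhibitor replicate 2. MET rose by 0.84 ± 0.16 (adjusted p = 0.00069). EGFR rose by 0.35 ± 0.12 (adjusted p = 0.0472). That call ended when parental replicate 2 or any array of the resistant or inhibitor groups was left out (adjusted p = 0.0524 to 0.176; range over 20 alternatives, 0.0247 to 0.176). It also ended with 50 added to the intensities, with the arrays of these groups alone, and with the UniGene rows kept (adjusted p = 0.0509, 0.0514 and 0.052).

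Of the 20 integrin and laminin genes, 9 rose and 4 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.00624, adjusted p = 0.125 with an estimated correlation), with ITGA2 at 2.49, LAMB3 at 1.96, ITGB4 at 1.87 and LAMA4 at -1.44. Of the 12 squamous and basal markers, 4 rose and 2 fell in both counts (camera adjusted p = 0.0131, adjusted p = 0.1 with an estimated correlation). The serpin gene SERPINB5 rose by 2.57 and TP63 by 1.59, SOX2 fell by 0.73, and the call ended with dim genes left out (adjusted p = 0.0618; range over 20 alternatives, 0.0058 to 0.1). Of the 16 lung lineage genes, 4 rose and none fell in both counts (camera adjusted p = 0.0194, adjusted p = 0.0927 with an estimated correlation): FOXA2 by 1.85, MUC1 by 1.35, HOPX by 0.92 and FOXA1 by 0.54. Of the lung lineage genes 1 fell without resistant replicate 1. Of the 15 stress response genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0323, adjusted p = 0.102 with an estimated correlation), with TRIB3 at 0.91 and DDIT4 at 0.63. The 1 that fell was not called without resistant replicate 2 or 3 or inhibitor replicate 3. The stress call ended without resistant replicate 3 or inhibitor replicate 3 (adjusted p = 0.0625 and 0.0784) and with dim genes left out (adjusted p = 0.173; range over 20 alternatives, 0.00891 to 0.173).

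Of the 22 proliferation genes, 7 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.00688, adjusted p = 0.159 with an estimated correlation). The mitotic genes CCNB1, CDC20 and BIRC5 fell by 0.88, 0.83 and 0.82, and the replication gene PCNA rose by 0.72. Of the 15 cholesterol synthesis genes, 5 fell and none rose in both counts (camera adjusted p = 0.00777, adjusted p = 0.125 with an estimated correlation), among them INSIG1 (-0.60) and FDPS (-0.55). Without inhibitor replicate 2, 1 of them rose. Of the 17 detoxification genes, 5 fell and 2 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.0927 with an estimated correlation). AKR1C3 fell by 2.40 and ALDH3A1 by 1.56, whereas ALDH1A3 rose by 1.90 and ABCC3 by 1.14.

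No other list was called with the inhibitor against resistant cells. Hypoxia and glycolysis genes had 5 of 15 higher and 2 lower (7 and 2 adjusted over the list alone; adjusted p = 0.085), and were called without inhibitor replicate 2 (adjusted p = 0.0163) and with loess scaling (adjusted p = 0.0493; range over 20 alternatives, 0.0163 to 0.189). The 2 lower became 1 without parental replicate 2 or 3, resistant replicate 1 or 3 or inhibitor replicate 2, and none without resistant replicate 2. Cytokine genes had 3 of 20 higher and 7 lower (3 and 8 adjusted over the list alone; adjusted p = 0.0921), with PTGS2 at 2.10 and IL11 at -1.54. Antigen presentation genes had 3 of 12 higher and 1 lower in both counts (adjusted p = 0.116). The 1 lower was lost without resistant replicate 2 or 3 or inhibitor replicate 2. YAP targets had 2 of 12 higher and 3 lower (2 and 5 adjusted over the list alone; adjusted p = 0.156), with CCN1 at -0.85. BCL2 family genes had 3 of 13 higher and 2 lower in both counts (adjusted p = 0.594), with the survival gene BCL2L1 at 0.98 and BAX at -0.70. Bypass receptor genes had 4 of 20 higher and 2 lower in both counts (adjusted p = 0.552). Neuroendocrine markers had 1 of 10 lower in both counts (adjusted p = 0.379), leukocyte markers 2 of 12 lower (1 adjusted over the list alone; adjusted p = 0.171) and endothelial markers 2 of 10 higher in both counts (adjusted p = 0.16). The 2 leukocyte markers became 1 without any 1 array except inhibitor replicate 2, as CD68 (adjusted p = 0.049) then had adjusted p-values of 0.0585 to 0.212 (range over 20 alternatives, 3.9e-05 to 0.212). The 2 endothelial markers became 1 without any 1 parental array, resistant replicate 1 or 2 or inhibitor replicate 1 or 3, as CDH5 (adjusted p = 0.0454) then had adjusted p-values of 0.0513 to 0.25 (range over 19 alternatives, 0.0115 to 0.25).

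**Figure D2:**
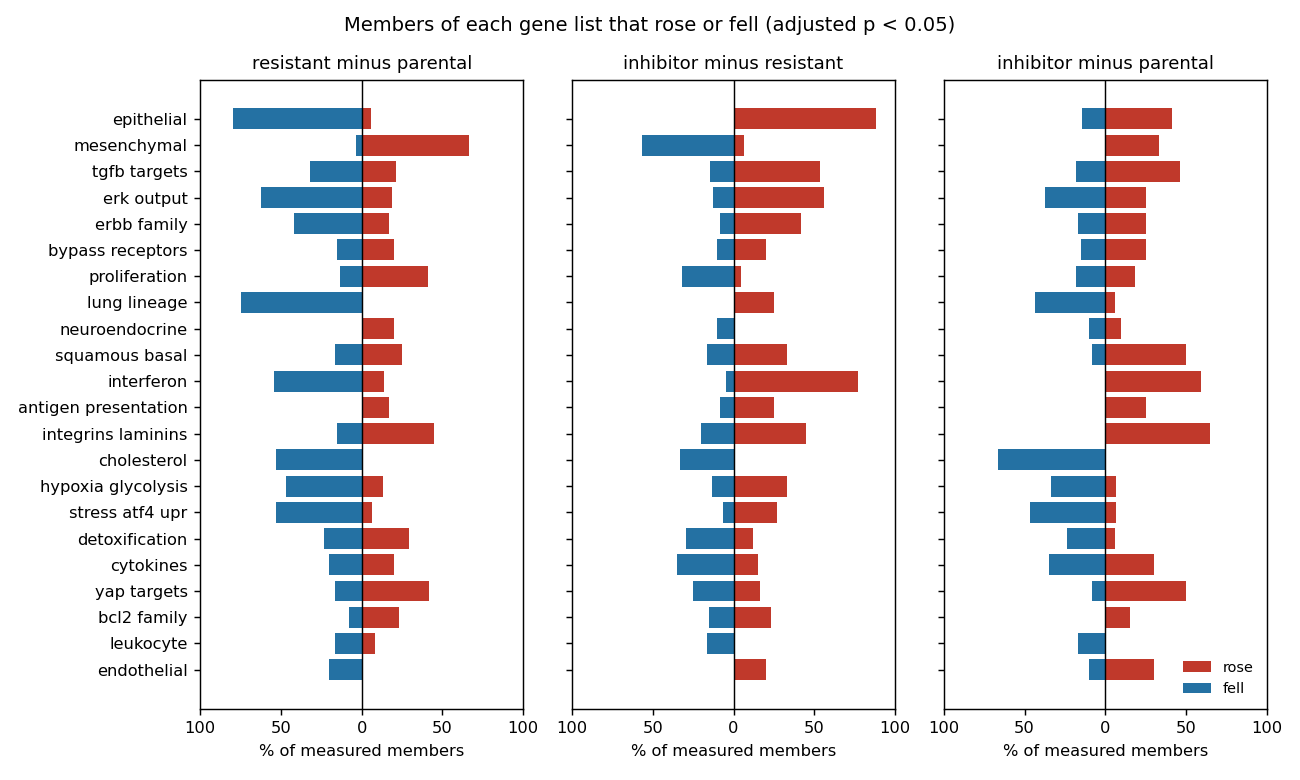
Percent of the measured members of each of the 22 gene lists that rose (red, to the right) or fell (blue, to the left) at an adjusted p under 0.05, in each of the 3 comparisons. In the epithelial list 27 of 34 genes fell in resistant cells and 30 of 34 rose with the inhibitor against resistant cells.

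Of the 788 genes that changed at least 2-fold in resistant cells, 641 (81.3%) changed the opposite way with the inhibitor. Among genes that had risen the share was 280 of 319 (87.8%), and among genes that had fallen 361 of 469. Independent lists of these sizes would share 28.1 and 40.7 genes. Those numbers treat all 30672 genes as equally likely to be called. Only 52.9% of genes had a mean above background, so the numbers are likely too low. With the measured resistance changes and no inhibitor effect, simulated arrays gave a mean of 0.02 genes called the opposite way and at most 1. Without an inhibitor effect the second comparison has almost no calls, so such a low count was fixed in advance. It does not show how many genes an inhibitor effect unrelated to resistance would give. Across all genes the changes of the first and second comparison correlated at -0.661, against a mean of -0.499 simulated without any change, and their covariance was -0.0700 against -0.00265. The simulated covariance includes independent noise of the shared arrays and went no further than -0.00277. This argues against such noise as the source of most of the observed covariance. Genes are not independent replicates, and 3 resistant arrays cannot be split into parts of at least 2. A deviation common to all 3 resistant arrays was not simulated, so part of the excess may come from that.

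COL8A1, ACKR3, NNMT, EMP3, CLDN11 and TCN1 were among the genes called the opposite way. COL8A1 stood at 84.9 ± 1.19 in parental, 1442 ± 56 in resistant and 95.1 ± 1.91 in inhibitor cells, and its level with the inhibitor was not called against the parental one (adjusted p = 0.226; range over 20 alternatives, 0.00911 to 0.402). The opposite was seen for SCGB3A1, CST1, CST4, TMEM100, NAPSA and the cell adhesion gene NTM, which fell in resistant cells and were still called lower than parental with the inhibitor. TMEM100 stood at 1464 ± 93.9 in parental, 125 ± 2.98 in resistant and 125 ± 4.56 in inhibitor cells. SCGB3A1 fell further with the inhibitor, by 0.47.

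Of the 788 genes, 233 were called the opposite way and not called against parental cells, 368 were called the opposite way and still called on the same side of parental, and 40 were called on the other side. A further 117 were not called the opposite way and still differed from parental, 29 were called further away, and 1 passed neither test. The labels do not settle the order of the treatments, so the arrays cannot show whether a change had arisen and reversed or had not arisen. Nor can the arrays tell the inhibitor apart from a possible separate selection of those cells. The inhibitor-minus-resistant change in the opposite direction, as a share of the resistant-minus-parental change, had a median of 72.2% for genes that had risen (quartiles 45.9% and 95.2%) and 50.4% for genes that had fallen (21.7% and 80.9%). Of 19 epithelial genes in this set, 18 were called the opposite way, with a median share of 106% (21.7% to 164%), and 5 were still called on the same side of parental. Of 13 mesenchymal genes 12 were called the opposite way, with a median of 95.4% (11.8% to 104%), and 5 were still called on the same side, among them CDH2 and AXL. Of 7 lung lineage genes 4 were called the opposite way, with a median of 19.9%, and 5 were still called lower than parental. All 5 interferon genes in the set were called so, with a median of 130%. All 4 ERK output genes were called so, with a median of 45.7%, and all 4 still differed from parental. Of 6 TGFβ targets 4 were called so, with a median of 47.4% (-114% to 94.9%), and 5 were still called on the same side of parental.

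**Figure D3:**
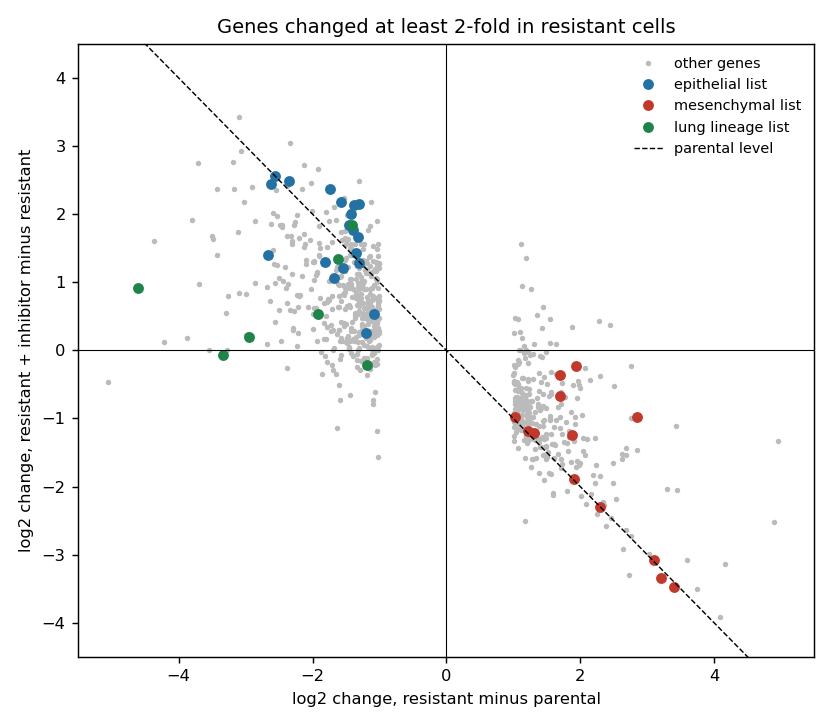
Log2 change with the inhibitor against resistant cells (vertical axis) plotted on the log2 change of resistant against parental cells (horizontal axis) for the 788 genes changed at least 2-fold in resistant cells; each point is 1 gene and the dashed line marks the parental level. The share of the resistance change that the inhibitor change offsets has a median of 106% (21.7% to 164%) for epithelial genes (blue), 95.4% (11.8% to 104%) for mesenchymal genes (red) and 19.9% (-18.1% to 131%) for lung lineage genes (green).

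The third comparison asked what still set the inhibitor cells apart from parental cells. Integrin and laminin genes were higher (13 of 20), and lung lineage (7 of 16) and cholesterol synthesis genes (10 of 15) were lower, with camera adjusted p-values of 2.99e-09 or less. The serpin gene SERPINB5 was 3.02 ± 0.09 higher on the log2 scale (8.10-fold, adjusted p = 7.07e-14), at 870 ± 89.8 against 107 ± 1.22 (SD, n = 3). SCGB3A1 fell by 5.53 ± 0.09 (adjusted p = 7.48e-18), to 81.7 ± 2.14, within background.

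Other large rises were those of ADAM19 (2.82), the laminin gene LAMB3 (2.78), the insulin-like growth factor binding gene IGFBP7 (2.73) and the interferon-induced gene EPSTI1 (2.67). The other large falls were those of CST1 (-4.09), CST4 (-3.69), HOPX (-3.69), TMEM100 (-3.55) and NAPSA (-3.41). Over all genes, 2186 were called higher and 2391 lower than in parental cells (14.9%), of which 182 were at least 2-fold higher and 240 at least 2-fold lower. Without inhibitor replicate 2 the counts were 2468 and 2510, and 171 and 224 by at least 2-fold.

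Of the 20 integrin and laminin genes, 13 rose and none fell (14 and none adjusted over the list alone; camera adjusted p = 7.82e-11, adjusted p = 0.0168 with an estimated correlation). After LAMB3 came ITGB4 (2.14), LAMB1 (1.53) and LAMA4 (1.24). Of the 30 mesenchymal markers, 10 rose and none fell in both counts (camera adjusted p = 0.000113, adjusted p = 0.0168 with an estimated correlation). AXL was 1.87 ± 0.14 higher, CDH2 1.71 ± 0.10, the matrix gene SPARC 1.34, TWIST1 1.04 ± 0.07 and VIM 0.64 ± 0.09. FN1 and ZEB1, within background, did not pass (adjusted p = 0.906 and 0.144). SNAI2 rose by 0.43 ± 0.13 (adjusted p = 0.0229). Its call ended without parental replicate 2 or 3 or inhibitor replicate 1 or 2 (adjusted p = 0.0502 to 0.0907) and with the arrays of these groups alone (adjusted p = 0.0625; range over 20 alternatives, 0.00329 to 0.0907).

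Of the 34 epithelial markers, 14 rose and 5 fell (16 and 7 adjusted over the list alone; camera adjusted p = 0.0127, adjusted p = 0.101 with an estimated correlation). That call also ended with dim genes left out (adjusted p = 0.0569; range over 20 alternatives, 0.00485 to 0.101). The 14 that rose became 9 without parental replicate 1. The keratin genes KRT8, KRT18 and KRT7 rose by 1.48, 1.32 and 1.15, and PRSS8 fell by 1.27. CDH1 was 0.57 ± 0.12 higher (adjusted p = 0.00161), while EPCAM (0.08, adjusted p = 0.708) and ESRP1 (adjusted p = 0.974) did not pass. Of the 12 squamous and basal markers, 6 rose and 1 fell in both counts (camera adjusted p = 0.00192). That call ended at an adjusted p = 0.0508 with an estimated correlation. They included SERPINB5, with TP63 at 0.85 and SOX2 at -1.83. Of the 16 lung lineage genes, 7 fell and 1 rose in both counts (camera adjusted p = 2.99e-09, adjusted p = 0.0118 with an estimated correlation), with SLC34A2 at -2.76 and NKX2-1, a lung lineage transcription factor gene, at -1.40. FOXA2 was the 1 that rose, by 0.44.

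Of the 15 cholesterol synthesis genes, 10 fell and none rose in both counts (camera adjusted p = 2.42e-10, adjusted p = 0.0168 with an estimated correlation). INSIG1 fell by 1.22 and FDFT1 by 0.83. Of the 15 stress response genes, 7 fell and 1 rose in both counts (camera adjusted p = 0.00226, adjusted p = 0.0457 with an estimated correlation), with DDIT4 at -0.81, ASNS at -0.59 and XBP1 at -0.55. The 7 that fell became 4 without parental replicate 2, and the 1 that rose was lost without parental replicate 3 or inhibitor replicate 1. Of the 22 interferon response genes, 13 rose and none fell (15 and none adjusted over the list alone; camera adjusted p = 6.7e-09, adjusted p = 0.0934 with an estimated correlation), with IFIT1 at 1.33, IFIT3 at 0.97 and MX1 at 0.91.

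Of the 28 TGFβ targets, 13 rose and 5 fell (14 and 6 adjusted over the list alone; camera adjusted p = 0.00192, adjusted p = 0.0508 with an estimated correlation). ADAM19 rose by 2.82, whereas ID3 fell by 2.21 and ID2 by 2.06. SMAD7 rose by 0.43 ± 0.09 (adjusted p = 0.00136), while TGFB2 (0.04, adjusted p = 0.86) and TGFBI (0.04, adjusted p = 0.783) did not pass. Of the 12 YAP targets, 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00192, adjusted p = 0.0457 with an estimated correlation), with the tissue factor gene F3 at 0.97 and CCN1 at 0.63. ERBB3 was still 1.28 ± 0.14 below its parental log2 level (adjusted p = 1.71e-06), and EGFR (-0.24, adjusted p = 0.229) and MET (0.30, adjusted p = 0.265) did not pass.

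Smaller shifts, each lost with an estimated correlation and with dim genes left out, were seen in 4 lists. BCL2 family genes had 2 of 13 higher (3 adjusted over the list alone), BCL2L1 by 0.82 and BMF by 0.52 (camera adjusted p = 0.0229, adjusted p = 0.0897 with an estimated correlation, 0.0772 without dim genes, 0.0167 to 0.0897 over 20 alternatives). These became 4 without inhibitor replicate 2. Antigen presentation genes had 3 of 12 higher (4 higher and 1 lower adjusted over the list alone), led by TAP2 at 0.72 (camera adjusted p = 0.0269, adjusted p = 0.101 with an estimated correlation, 0.0659 without dim genes, 0.0739 without inhibitor replicate 2, 0.0133 to 0.101 over 20 alternatives). Without parental replicate 3 or inhibitor replicate 1, 1 was lower over all genes. Hypoxia and glycolysis genes had 5 of 15 lower and 1 higher (7 and 2 adjusted over the list alone), led by NDRG1 at -0.91 (camera adjusted p = 0.0354, adjusted p = 0.101 with an estimated correlation, 0.132 without dim genes, 0.0663 without parental replicate 2, 0.205 without inhibitor replicate 2, 0.0199 to 0.205 over 20 alternatives). The 1 higher was lost without inhibitor replicate 1 and became 4 without inhibitor replicate 2. Leukocyte markers had 2 of 12 lower in both counts, the class II chaperone gene CD74 by -1.90 and the lipopolysaccharide receptor gene CD14 by -1.72, both of which lung epithelial cells also express. The camera adjusted p of that list was 0.0285 (adjusted p = 0.0934 with an estimated correlation, 0.0576 without dim genes, 0.0545 without a trend, 0.0614 without inhibitor replicate 1, 0.012 to 0.0934 over 20 alternatives). Its median was -0.024, and 0.0022 without inhibitor replicate 1.

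The other lists were not called against parental cells. ERK output genes had 4 of 16 higher and 6 lower (6 and 6 adjusted over the list alone; adjusted p = 0.673), with PHLDA1 at 1.40 and EGR1 at -1.08. ERBB family genes had 3 of 12 higher and 2 lower in both counts (adjusted p = 0.684; median 0.0012, mean -0.0043, test upward). The 2 lower became 1 without any 1 array except inhibitor replicate 2. Bypass receptor genes had 5 of 20 higher and 3 lower in both counts (adjusted p = 0.161), proliferation genes 4 of 22 higher and 4 lower in both counts (adjusted p = 0.673), and detoxification genes 1 of 17 higher and 4 lower in both counts (adjusted p = 0.125), with ALDH3A1 at -2.59. The higher proliferation genes became 1 without parental replicate 1 and 2 without inhibitor replicate 3, and the lower detoxification genes 2 without parental replicate 2 or 3. Cytokine genes had 6 of 20 higher and 7 lower in both counts (adjusted p = 0.494), with CXCL8 at -2.15 and CCL2 at -1.61. Neuroendocrine markers had 1 of 10 higher and 1 lower in both counts (adjusted p = 0.744; median 0.00033, mean -0.017, test downward). The higher marker, CHGB, was lost without parental replicate 1 or 3, resistant replicate 3 or any 1 inhibitor array. The lower one, ENO2, was lost without parental replicate 2 or inhibitor replicate 1. Endothelial markers had 3 of 10 higher and 1 lower (3 and 2 adjusted over the list alone; adjusted p = 0.673; median -0.0066, mean 0.022, test upward). The 3 higher became 1 without parental replicate 2, where CDH5 had an adjusted p of 0.0936 (range over 19 alternatives, 0.00966 to 0.213) and TEK of 0.124 (range over 19 alternatives, 0.0163 to 0.124). The 1 lower was lost without parental replicate 1 or 3 or inhibitor replicate 2.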

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

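Of the alternatives in this part, normexp background correction and the UniGene rows were chosen after seeing the data. At an adjusted p under 0.01, by construction a stricter threshold, 1758 genes were higher and 1749 lower with the inhibitor than in resistant cells, 1400 were higher than in parental cells, and 76.5% of the genes changed at least 2-fold on resistance were called the opposite way with the inhibitor. With each array left out in turn, that share ranged from 76.6% to 81.2%, with fewer arrays in the fit by construction. All other counts of called genes stayed within 1.5 times their reported value in the alternatives run. Genes at least 2-fold higher in resistant cells numbered 226 with 50 added to the intensities and 402 with normexp background correction. The opposite changes were not run with only the arrays of the compared groups, which was not planned. Of 322 results of named genes, 32 crossed the threshold in at least 1 alternative, and of 66 results of lists, 27 did; no call turned to the opposite direction in its test. List medians near 0 did change sign, such as that of the leukocyte list against parental cells, from -0.024 to 0.0022 without inhibitor replicate 1. Over lists and alternatives, a list call was lost 49 times, 26 of them with an estimated correlation and 11 of them with dim genes left out. With the replicate block, 2944 genes were higher and 2975 lower in resistant than parental cells, and 79.8% were called the opposite way with the inhibitor. Correlations of same-numbered arrays' deviations lay between -0.198 and 0.0292, and 0 arrays correlated best with their own number, so the numbers were not taken to pair the arrays. With that block 6 results of named genes no longer passed, among them EGFR with the inhibitor against resistant cells (adjusted p = 0.0715; range over 20 alternatives, 0.0247 to 0.176). Signal over background limits the changes of dim genes, since background was not subtracted.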

Other observations

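The tests of related sequence and of pseudogene rows, those of the TGFβ target list and those of the lung lineage list were chosen after their results were seen; those of a mixture, of growth state and of the splits were written before. The genes of the next paragraphs were also chosen after their values were seen.

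Of 19 measured genes tied to class II antigen presentation to helper T cells, counting the transactivator gene CIITA, 6 had a group mean over 2 times background. Of these 6, 5 were called lower with the inhibitor than in resistant cells, 5 lower than in parental cells, and 4 were already lower in resistant than in parental cells; the set was not tested for enrichment. The invariant chain gene CD74 stood at 1456 in parental, 843 in resistant and 396 in inhibitor cells (n = 3 each). HLA-DRA stood at 566, 401 and 187, HLA-DMA at 645, 361 and 256, HLA-DMB at 326, 176 and 104, and HLA-DPA1 at 353, 325 and 89.6. HLA-DRB3, the sixth, was not called. The class II transactivator gene CIITA lay within background in all groups.

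Some genes lay outside both other groups with the inhibitor: 65 were at least 2-fold higher than in resistant and in parental cells, and 22 at least 2-fold lower. Without inhibitor replicate 2 these counts were 56 and 23, of which 51 and 20 were shared. Higher were SERPINB5 (2.57 against resistant and 3.02 against parental cells on the log2 scale), the cadherin gene CDH6 (2.06 and 2.35), the kallikrein gene KLK5 (2.53 and 1.80) and the transcription factor gene ISL1 (2.25 and 1.95). The integrin gene ITGB4 was 1.87 and 2.14 higher, and 1.54 and 1.80 higher without inhibitor replicate 2. Lower were EPDR1 (-2.56 and -2.78), GPNMB (-2.50 and -2.00) and the aldehyde dehydrogenase gene ALDH3A1 (-1.56 and -2.59).

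Inhibitor replicate 2 stood apart from the other arrays of its group, with 54 genes deviating at least 2-fold, among them ZNF735 (758 against 174) and RPL32P11 (815 against 225). A mixture with parental or resistant material is argued against, since those directions held an R squared of 0.00235 of its deviation. For growth state, the median deviation of the proliferation list was 0.0957 (95% interval -0.0584 to 0.196). This only just met the bounds set beforehand for arguing against growth state. Of the 22 lists, only antigen presentation had a larger median deviation (0.130), so growth state stays open. Pseudogene rows in general shifted by 0.0404 more than protein-coding rows, less in size than the same difference between replicates 1 and 3 (-0.0564). Among bright genes, 17.8% of the 45 deviating ones were pseudogenes against 8.19% of the others (Fisher's exact test, two-sided, p = 0.0289; odds ratio 2.42, 95% interval 0.970 to 5.32), but that test was made after many of these genes had been seen, its interval includes 1 and no probe sequence was used, so related transcripts stay open. Other biological explanations were not tested.

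The TGFβ target list was higher with a TGFβ receptor inhibitor than in resistant cells. The list holds ligand, receptor and feedback inhibitor genes and was not split by the direction in which TGFβ acts on a member. Its shift is therefore no measure of pathway activity. The call does not rest on inhibitor replicate 2, since camera gave an adjusted p of 1.46e-05 without it (range over 20 alternatives, 1.28e-05 to 0.0369, the highest with an estimated correlation). Of the 15 targets that rose, 46.7% had been called lower in resistant cells. Whether these targets rose together with the epithelial genes or on their own cannot be told apart, since the share lies between the bounds set. Over the 28 targets, the changes of the first and second comparison correlated at -0.491. Comparisons that share a group give -0.5 without any change. Many of these targets did change, so that value is no reference for them, and no other was simulated. The correlation therefore cannot decide it either. The labels do not state whether the inhibitor was present at harvest, which stays open.

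Among genes at least 2-fold lower or higher in resistant cells, the inhibitor change offset a median of 19.9% of the resistance change in the lung lineage list (7 genes) and 106% in the epithelial list (19 genes). These lists were picked for the contrast after their shares were seen, so a permutation test of the gap made afterwards (p = 0.00118, two-sided, 100000 resamples) does not exclude chance. The gap was 0.829 with background correction and 0.857 without, which met the bound set for arguing against values near background as its whole cause. That correction added an offset of 50, which keeps changes near background compressed, so it cannot decide this. Chance choice of the lung genes stays open: against all fallen genes, whose median was 50.4%, 5.12% of 10000 random sets had a median as low. Whether the changes reversed or had not arisen was not tested.

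In each comparison 1 of the 10 splits of the 6 arrays, the real one, gave as many genes. The real splits gave 7441 genes for resistant against parental cells, 4829 for the inhibitor against resistant cells and 3869 for the inhibitor against parental cells, and the highest other split gave 0 in each. With 10 splits the share cannot fall under 0.1, so the splits are too few.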
